A study of Homo sapiens with 6 samples.

How the data were processed

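Total RNA from 6 samples of THP-1 cells differentiated with PMA was sequenced, 3 untreated and 3 exposed to native LDL at 0.5 mg/mL for 24 h in medium with 10% serum. Per the labels' protocols, libraries were made with the NuGEN Ovation Human FFPE RNA-Seq Multiplex system. The authors deposited raw counts of reads per gene as whole numbers for 46896 genes of the hg19 build, with gene identifiers, symbols, biotypes and coordinates in the same table. Per the submitters' processing notes, reads were handled with FastQC, STAR 2.5.3a and featureCounts 1.15.2. The strand setting, the treatment of reads that map to several places and the annotation release are not given in the sources used here. Some members of the fixed lists and 1 gene of the naming rule were not analysed here.

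Groups and replicate numbers came from the sample titles. The labels state 3 samples per group without saying that they were separate cultures, so p values measure the spread between these samples, which may be technical. The libraries were checked for duplicates by a chi-square test of counts over genes, and every pair within a group differed (2.43 to 14.01 per degree of freedom).

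Genes with too few counts were removed with edgeR's filterByExpr (minimum count 10, minimum total 15), which kept 13423 genes (11838 protein coding) of the 34250 with at least 1 read and left out at most 0.33% of the reads of a library. Counts were scaled by TMM (factors 0.967 to 1.036). The main test was edgeR 4.0.16 in R 4.3.3, with glmQLFit (robust) and glmQLFTest on group alone over all 6 libraries, two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Standard errors of log2 fold changes were computed from the Fisher information of the fit and its quasi-likelihood variance. CPM values are TMM-scaled, and their errors are SDs over 3 libraries. Counting error per library is set by totals of 3675479 to 12421189 reads. The common biological coefficient of variation was 7.8%.

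A set of 24 gene lists was fixed before the data were examined. Lists with at least 5 measured members were compared with all other tested genes by limma 3.58.1 camera on log2 CPM (prior count 2) with a preset correlation of 0.01, two-sided, adjusted by Benjamini-Hochberg over the 24 lists. Camera with an estimated correlation, cameraPR and fry were alternatives. A further 7 gene families were drawn up after the genes with the largest changes had been seen, and are described only among the additional observations.

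The rule for naming genes, also fixed before the data were examined, took the 10 largest changes in each direction among genes past the threshold with a mean of at least 5 CPM in the higher group, a gene symbol and no overlap between the groups. It also took up to 4 members of each list with the lowest p, up to 2 abundant members of each list that did not pass, and a short set of sterol, lipid and cytokine genes. It gave 161 genes. Of these, 4 that passed and 50 that did not are not reported here. Genes chosen after their values were seen were LBR, PMVK, ERLIN2, MYLIP, GRAMD1B, LIPA, NR1H2, SCD, PLTP, ACACA, PPARG, ACADM, UCP2, FABP5, CPT1A, ANGPTL4, LRPAP1, CXCL16, SCARB2, LRP8, CTSL, IL8, IL1RN, CSF1, CCL8, GBP2, PYCARD, PHGDH, PSAT1, GPX1, HSPA8, HSPB1, JUN, LYZ and MMP9, in most cases because they moved against the rest of their list, and the members of the later families named among the additional observations.

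A set of 164 genes was followed through the alternatives, except where a filter removed one. The adjusted p below 0.01 and the tested fold change of at least 1.5 were not applied to them. Of these genes, 41 overlap another tested gene in the annotation and 25 overlap a protein-coding one. Without a stated strand setting, reads of overlapping genes cannot be told apart. This applies to SREBF1, NR1H3, FADS2, ACADVL, ACADM, SOD2, ACAT2, LIPA, CXCL16, RSAD2, CASP1, PLTP, ACSS2 and NR1H2 among others. Histone, ribosomal protein, MHC class II and Fc receptor genes have near-identical copies, which makes their single values uncertain.

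The procedure was tested on simulated data for nLDL against untreated with 13230 genes, made from the means and library sizes of the real samples. It recovered 34 of 65 genes changed 1.5-fold (52.3%), 55 of 65 changed 2-fold (84.6%) and 63 of 64 changed 4-fold (98.4%), with 5 false calls (3.18% of calls). Intervals from the standard errors covered the true value in 94.4% of the better-counted genes. Genes with few simulated reads over all libraries were left out of that share. With the changed genes placed at random, 0 of the 24 lists were called. The simulated genes were drawn independently, so this cannot test the preset correlation on which the list calls depend. The simulation changed a far smaller share of genes than was called in the real comparison, and held no shift of the third libraries. Its shares of recovered genes and false calls may therefore differ from those in the real comparison.

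Alternatives tried were DESeq2 1.42.0 size factors, the total count alone, TMM without mitochondrial and the 20 most abundant genes, no filter on low counts, at least 1 or 5 CPM in 3 samples, the DESeq2 Wald test, limma-voom, the edgeR likelihood ratio test, a fit without robust dispersion, the replicate number as a block, an adjusted p below 0.01, a tested fold change of at least 1.5, and each library left out in turn. Leaving out the third library of both groups, and a term for those libraries in the fit, were added after seeing the data. Figures were drawn with matplotlib 3.10.9.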

Results

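RNA was sequenced from macrophages made from THP-1, an established human monocytic leukaemia line that the phorbol ester PMA turns into adherent, macrophage-like cells. After 48 h in 5 ng/mL PMA and 24 h without it, 3 samples received medium containing native low-density lipoprotein (nLDL, the unmodified cholesterol-carrying particle of plasma) at 0.5 mg/mL, and 3 received the same medium without it. RNA was taken 24 h later. The comparison asks how the transcriptome of these cells differs after exposure to nLDL.

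Reads assigned to genes numbered 11520593, 12421189 and 5558746 in untreated samples 1, 2 and 3, and 8972289, 10907465 and 3675479 in nLDL samples 1, 2 and 3. A single read stood for 0.0779 to 0.276 CPM (counts scaled by library size and TMM), and between 19313 and 25932 genes had at least 1 read. The third library of each group was the shallowest of its group and differed from the others in composition. Mitochondrially encoded genes took 6.83% of reads in untreated 3 and 5.58% in nLDL 3 against 3.53% to 4.1% elsewhere, and the signal recognition particle RNA RN7SL1 took 1.23% and 1.25% against 2.18% to 2.3% (95% Wilson intervals within 0.024 percentage points of each share, covering counting error only). Across genes, log2 CPM correlated at 0.983 to 0.991 within groups and at 0.967 to 0.978 between them. The first principal component (53.8% of the variance) separated nLDL from untreated samples, and the second (19.2%) separated the third library of each group from the rest.

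**Figure D1:**
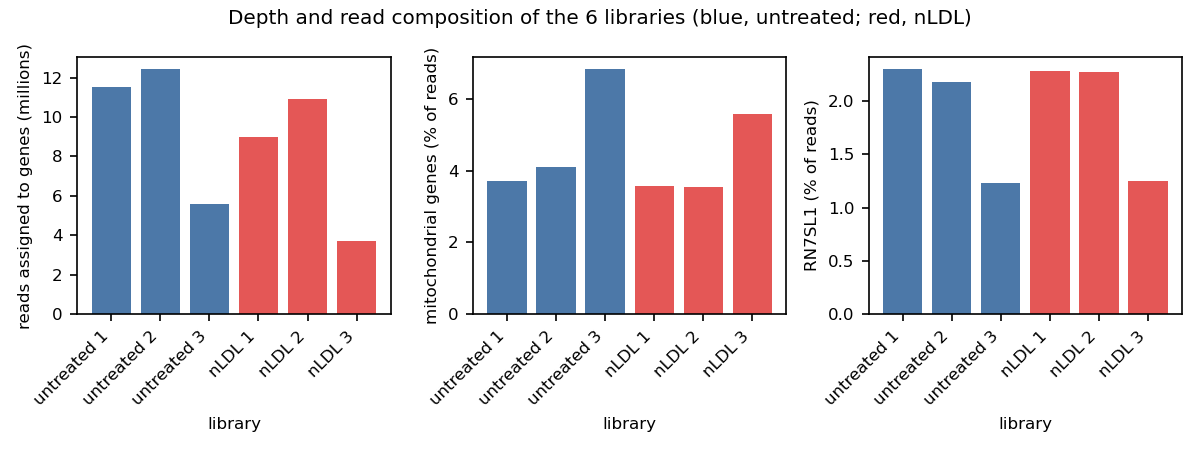
Bars give, for each of the 6 libraries (blue, untreated, and red, nLDL), the reads assigned to genes, the percentage of reads on mitochondrially encoded genes and the percentage on RN7SL1. The third library of each group had the fewest reads of its group (5558746 and 3675479), the highest mitochondrial share (6.83% and 5.58%) and the lowest RN7SL1 share (1.23% and 1.25%).

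Macrophages given nLDL carried more transcripts of cytokine and other NF-kB-linked genes, cholesterol synthesis enzymes and a list of lipid droplet genes and PPAR targets. They carried fewer transcripts of cell cycle genes, histones and several lipoprotein and scavenger receptors. These 6 lists passed in camera with a preset correlation, and each had adjusted p = 0.14 with an estimated correlation. PLIN2, the main coat protein of lipid droplets in macrophages, rose from 639.2 ± 71.5 to 2289 ± 278 CPM (mean ± SD, n = 3 per group), a 3.58-fold difference. IL1B, the gene of interleukin-1 beta, rose 3.20-fold, from 262.7 ± 13.0 to 839.6 ± 33.5 CPM. HMGCS1, an early enzyme of the mevalonate pathway, rose 2.40-fold from 65.9 ± 6.88 to 157.5 ± 3.02 CPM. The lipid-sensing receptor TREM2 was 2.29-fold lower (222.7 ± 4.91 to 96.7 ± 5.94 CPM) and the cholesterol efflux transporter ABCG1 was 2.06-fold lower (30.7 ± 3.99 to 15.1 ± 0.393 CPM).

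In hg19, PLIN2 (ENSG00000147872.5) lies on chromosome 9 from 19108373 to 19149288, IL1B (ENSG00000125538.7) on chromosome 2 from 113587328 to 113594480 and HMGCS1 (ENSG00000112972.10) on chromosome 5 from 43289497 to 43313614. TREM2 (ENSG00000095970.12) lies on chromosome 6 from 41126244 to 41130924 and ABCG1 (ENSG00000160179.14) on chromosome 21 from 43619799 to 43717354. All of these are protein-coding genes and the counts were of reads per gene. By edgeR's quasi-likelihood test, the log2 fold changes and Benjamini-Hochberg adjusted p values were 1.84 ± 0.09 (SE) and 1.47e-09 for PLIN2, 1.68 ± 0.06 and 3.63e-12 for IL1B, and 1.26 ± 0.08 and 1.16e-09 for HMGCS1. The same test gave -1.20 ± 0.07 and adjusted p = 2.66e-10 for TREM2, and -1.04 ± 0.12 and 3.48e-06 for ABCG1. In each of these 5 genes all 3 nLDL libraries lay on one side of all 3 untreated libraries.

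Of 13423 genes tested, 1883 were higher and 1640 lower in nLDL samples at an adjusted p below 0.05, together 26.2% of the genes. At least 2-fold differences made up 437 of the higher and 199 of the lower genes, and at least 4-fold differences 84 and 4. The groups did not overlap in 95.6% of the changed genes, against 38.6% of all tested genes and the 10% that chance gives for 3 against 3. Scaling by the total count alone, without TMM factors, gave 1421 higher and 2354 lower genes, so that 37.6% of the changed genes were higher in place of 53.4%. Without nLDL 2 the genes lower numbered 1082.

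By the rule fixed for naming genes, the largest increases were in NCCRP1 (10.6-fold), ANO3 (10.4-fold), the secreted ligand WNT5A (9.59-fold, from 1.99 ± 0.763 to 19.3 ± 2.88 CPM), the tryptophan-degrading enzyme IDO1 (8.88-fold, 13.2 ± 4.32 to 113 ± 2.70 CPM), the chemokine receptor CCR7 (8.03-fold, 6.97 ± 2.32 to 56.7 ± 2.92 CPM), LAMP3 (8.03-fold), C1QTNF1 (7.33-fold), the C-type lectin CLEC4E (6.95-fold), the cytokine subunit IL23A (6.93-fold) and the nuclear receptor NR4A3 (6.64-fold). The largest decreases were smaller in size. They were S1PR1 (3.32-fold lower), NES, the gene of the intermediate filament nestin (3.22-fold), KCNQ1 (2.99-fold), ANK3 (2.97-fold), the fractalkine receptor CX3CR1 (2.94-fold, from 77.6 ± 4.36 to 27.3 ± 5.08 CPM), TM6SF1 (2.85-fold), LGI2 (2.85-fold), MRVI1 (2.84-fold), FAIM3 (2.81-fold) and the RNA-sensing receptor TLR7 (2.77-fold). Some of these folds rest on few reads in the lower group. Untreated means were 1.19 CPM for NCCRP1, 0.707 for ANO3, 0.944 for CLEC4E and 1.64 for C1QTNF1. Means in nLDL samples were 2.09 CPM for S1PR1 and 1.68 for TM6SF1. Adjusted p values of these 20 genes ran from 3.21e-10 for CCR7 to 0.000829 for TM6SF1 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

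**Figure D2:**
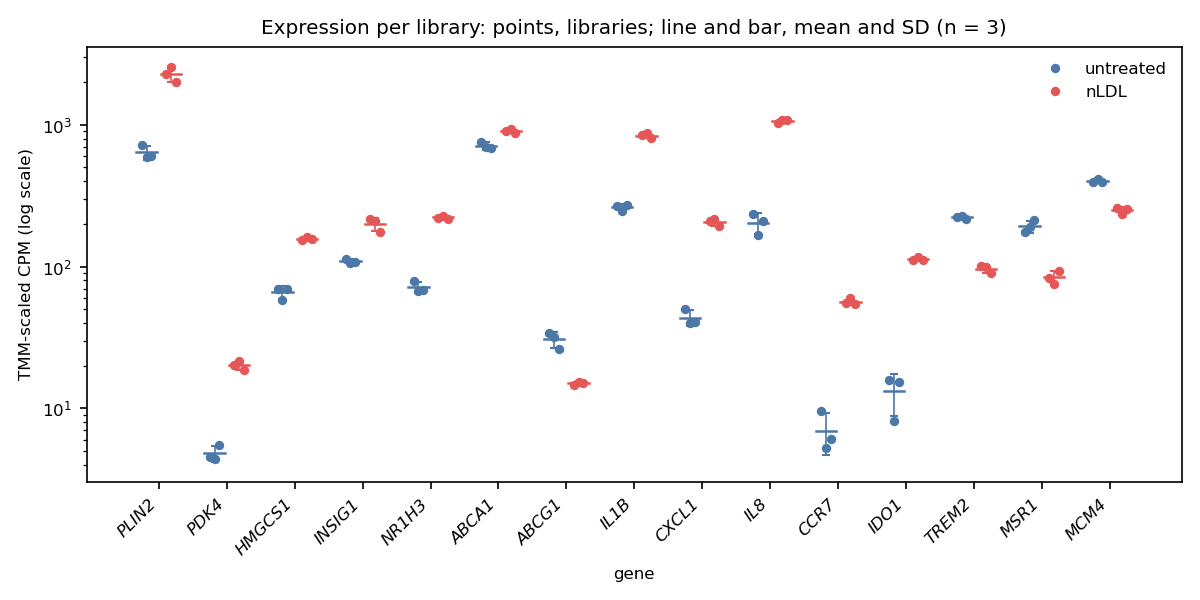
Each point is the TMM-scaled CPM of 1 library on a log axis (blue, untreated, and red, nLDL) for 15 genes named along the horizontal axis, with the mean as a line and the SD as a bar (n = 3 per group). All 3 nLDL libraries lay above all 3 untreated libraries for genes such as PLIN2, HMGCS1, IL1B and CCR7, and below them for ABCG1, TREM2, MSR1 and MCM4.

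Genes of the cholesterol synthesis pathway rose together. Of 19 measured members of that list 15 rose, 2 fell and 2 did not pass, and adjusted over the list alone the counts were also 15 and 2. The median log2 fold change was 0.63 (camera adjusted p = 4.27e-06 with a preset correlation, and adjusted p = 0.14 with an estimated correlation). Examples were LSS, which closes the sterol ring (2.45-fold), MVD (2.01-fold) and MSMO1 (1.79-fold). The members that fell were PMVK, a mevalonate pathway kinase (log2 fold change -0.47), and LBR, a sterol reductase of the inner nuclear membrane (-0.39). ACAT2 (-0.09 ± 0.13) did not pass, and it overlaps SOD2 in the annotation.

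Regulators of sterol uptake moved both ways. In that list 7 of 17 measured genes rose, 4 fell and 6 did not pass, with 7 and 4 adjusted over the list alone and a median of 0.08, or 0.02 without nLDL 2, 0.13 without untreated 1 and 0.16 without nLDL 1 (camera adjusted p = 0.22, and adjusted p = 0.32 with an estimated correlation). The sterol transporters GRAMD1A (3.39-fold) and STARD4 (1.67-fold), the sterol-sensing protein INSIG1 (1.84-fold, from 109.1 ± 4.28 to 199.7 ± 21.9 CPM) and the transcription factor SREBF2 (1.30-fold) rose. The members that fell were the ubiquitin ligase MYLIP (log2 fold change -0.61), ERLIN2 (-0.37), the lysosomal acid lipase LIPA (-0.33) and GRAMD1B (-0.53). The call of GRAMD1B was lost, at edgeR adjusted p values of 0.123 to 0.16, without untreated 2, nLDL 1 or nLDL 2.

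Targets of the oxysterol receptor LXR and efflux genes also went both ways. Of 16 measured members 4 rose, 7 fell and 5 did not pass, with 4 and 8 adjusted over the list alone. The median was -0.42 and the list did not pass (camera adjusted p = 0.0782, and adjusted p = 0.32 with an estimated correlation), although it did without nLDL 1 (median -0.25, camera adjusted p = 0.0342). The genes that rose were NR1H3, which encodes LXR alpha itself (3.10-fold, from 71.5 ± 6.61 to 222.2 ± 5.86 CPM), the efflux transporter ABCA1 (1.27-fold, 711.2 ± 42.3 to 905.9 ± 28.1 CPM), the desaturase SCD (log2 fold change 0.26) and NR1H2 (0.33). The calls of SCD and NR1H2 were lost without untreated 2 or nLDL 1, at edgeR adjusted p values of 0.0749 to 0.155, and that of NR1H2 also without nLDL 2 (0.104). Beside ABCG1, lipoprotein lipase LPL (2.43-fold), APOC1 (1.82-fold), PLTP (log2 fold change -0.58) and SREBF1 (1.33-fold) were lower. APOE had a log2 fold change of -0.42 ± 0.15 and did not pass, although it did without untreated 3 (-0.55, edgeR adjusted p = 0.00181) and without nLDL 1 (-0.52, 0.0225). It also passed with the replicate number as a block (-0.425, edgeR adjusted p = 4.87e-12) and with a term for the third libraries (-0.427, 3.97e-11).

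Lipid droplet genes and PPAR targets rose in 13 of 25 measured members, fell in 5 and did not pass in 7, with 16 and 5 adjusted over the list alone (median 0.40, camera adjusted p = 0.000328, and adjusted p = 0.14 with an estimated correlation). The median was 0.61 without untreated 1. Beside PLIN2, the droplet protein HILPDA (2.95-fold), the pyruvate dehydrogenase kinase PDK4 (4.32-fold, from 4.82 ± 0.639 to 20.1 ± 1.33 CPM), the mitochondrial acyl-CoA dehydrogenase ACADVL (1.90-fold), CPT1A, which admits fatty acids to mitochondria (log2 fold change 1.05), and ANGPTL4 (5.64-fold) rose. The 5 that fell were the receptor PPARG (-0.96), the medium-chain dehydrogenase ACADM (-0.69), UCP2 (-0.25), the fatty acid binding protein FABP5 (-0.20) and the fatty acid translocase CD36 (-0.19). The calls of UCP2 and CD36 were lost without untreated 2, nLDL 1 or nLDL 2 (edgeR adjusted p values of 0.0524 to 0.109), and that of FABP5 in all but 1 of the 6 fits that left out a library (0.0736 to 0.173). Fatty acid synthesis and desaturation genes rose in 8 of 18 measured members and fell in 2, with 9 and 2 adjusted over the list alone (median 0.25, camera adjusted p = 0.00912, and adjusted p = 0.14 with an estimated correlation). ACSL1, which activates fatty acids (1.78-fold), ME1 (1.53-fold), the desaturase FADS2 (1.75-fold) and ACSS2 (1.47-fold) rose. SREBF1 and the acetyl-CoA carboxylase ACACA (-0.23) fell, and the call of ACACA was lost without untreated 1, untreated 2, nLDL 1 or nLDL 2 (edgeR adjusted p values of 0.0548 to 0.235).

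Scavenger and lipoprotein receptors were mostly lower. Of 18 measured members 10 fell, 4 rose and 4 did not pass, with the same counts adjusted over the list alone (median -0.28, camera adjusted p = 0.0206, and adjusted p = 0.14 with an estimated correlation). TREM2, the class A scavenger receptor MSR1 (2.31-fold lower, from 192.1 ± 18.3 to 84.0 ± 8.93 CPM), and the sorting receptors SORT1 (2.17-fold) and SORL1 (1.79-fold) were among those that fell. The 4 that rose were the chaperone LRPAP1 (log2 fold change 0.46), CXCL16 (0.72), the lysosomal membrane protein SCARB2 (0.25) and LRP8 (0.24), whose call was lost without untreated 2, untreated 3, nLDL 1 or nLDL 2 (edgeR adjusted p values of 0.0527 to 0.142). Lysosomal genes rose in 15 of 34 measured members, fell in 2 and did not pass in 17, with 17 and 3 adjusted over the list alone (median 0.23, or 0.15 with scaling by the total count alone, camera adjusted p = 0.000215, and adjusted p = 0.14 with an estimated correlation). The proteases CTSB (1.74-fold, from 1052 ± 99.0 to 1830 ± 184 CPM) and CTSS (1.51-fold) and the proton pump subunits ATP6V1H (1.67-fold) and ATP6V1A (1.49-fold) rose, while LIPA (-0.33) and the protease CTSL (-0.28) fell. LIPA overlaps interferon-induced genes in the annotation.

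The list of cytokines, chemokines and other genes linked to NF-kB showed the largest list median, 1.51. Of 29 measured members 24 rose, 2 fell and 3 did not pass, with 24 and 2 adjusted over the list alone (camera adjusted p = 3e-15, and adjusted p = 0.14 with an estimated correlation). The neutrophil chemokines CXCL1 (4.71-fold, from 43.7 ± 5.38 to 206.2 ± 12.36 CPM) and IL8 (from 203.5 ± 35.0 to 1071 ± 29.95 CPM), the hyaluronan-binding protein TNFAIP6 (4.61-fold) and the mitochondrial superoxide dismutase SOD2 (3.87-fold) rose. The members that fell were the interleukin-1 receptor antagonist IL1RN (-0.23) and the growth factor CSF1 (-0.43). The call of IL1RN was lost without untreated 2, nLDL 1 or nLDL 2 (edgeR adjusted p values of 0.0778 to 0.119), and that of CSF1 in all 6 fits that left out a library (0.0673 to 0.127). The chemokines CXCL10 (-0.04 ± 0.15), CCL2 (-0.23 ± 0.15) and CCL8 (-0.37 ± 0.18) did not pass.

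Interferon-stimulated genes rose in 14 of 42 measured members, fell in 1 and did not pass in 27, with 14 and 2 adjusted over the list alone. The median was 0.13 (camera adjusted p = 0.00196, and adjusted p = 0.23 with an estimated correlation), and 0.05 with scaling by the total count alone. LY6E (1.60-fold), IFI27 (1.97-fold), the antiviral protein RSAD2 (1.41-fold) and the RNA sensor IFIH1 (1.31-fold) rose, and OAS3 (0.08, edgeR adjusted p = 0.365 with Benjamini-Hochberg adjustment) did not pass. GBP2 fell (-0.29), a call lost without untreated 1, untreated 2 or nLDL 2 (edgeR adjusted p values of 0.0819 to 0.199). Among 14 measured inflammasome genes 3 rose and 2 fell, also when adjusted over the list alone. Their median was -0.03, their mean 0.11, and the list did not pass (camera adjusted p = 0.601, and adjusted p = 0.62 with an estimated correlation). IL1B, NLRC4 (log2 fold change 0.59) and MEFV (0.39) rose. The protease CASP1 (-0.26) and the adaptor PYCARD (-0.45) fell, the former not without untreated 2, nLDL 1 or nLDL 2 (edgeR adjusted p values of 0.0539 to 0.129) and the latter not without untreated 1, untreated 2, nLDL 2 or nLDL 3 (0.0843 to 0.208).

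Genes of 3 stress and energy lists rose together. In the list for endoplasmic reticulum stress and the amino acid response 18 of 26 measured members rose and 2 fell, with the same counts adjusted over the list alone (median 0.37, camera adjusted p = 3.09e-05, and adjusted p = 0.14 with an estimated correlation). DDIT4 (2.22-fold), ATF3 (2.22-fold), EDEM1 (1.52-fold) and the chaperone HSPA5 (1.41-fold) rose, and the serine synthesis enzymes PHGDH (-0.56) and PSAT1 (-0.50) fell, the latter not without untreated 1, untreated 2, nLDL 1 or nLDL 2 (edgeR adjusted p values of 0.0512 to 0.198). Genes of oxidative stress and of its factor NRF2 rose in 16 of 27 measured members and fell in 1. Adjusted over the list alone the counts were 17 and 1. The median was 0.54 (camera adjusted p = 1.6e-07, and adjusted p = 0.14 with an estimated correlation). The cystine transporter SLC7A11 (4.59-fold, from 49.7 ± 7.52 to 229 ± 9.92 CPM), the pentose phosphate enzyme PGD (1.64-fold) and the reductase TXNRD1 (1.89-fold) rose, and the peroxidase GPX1 (-0.44) fell. Hypoxia and glycolysis genes rose in 18 of 27 measured members and fell in 0, with 20 and 0 adjusted over the list alone (median 0.48, camera adjusted p = 1.6e-07, and adjusted p = 0.32 with an estimated correlation). Examples were hexokinase HK2 (1.98-fold), ALDOC (2.06-fold), NDRG1 (1.63-fold) and BNIP3L (1.53-fold). Heat shock and immediate early genes rose in 7 of 21 measured members and fell in 4, also when adjusted over the list alone (median 0.03, camera adjusted p = 0.363, and adjusted p = 0.54 with an estimated correlation). The phosphatase DUSP1 (4.34-fold), NR4A3 and JUNB (log2 fold change 0.58) rose. KLF4 (-0.96), the chaperones HSPA8 (-0.28) and HSPB1 (-0.25), and JUN (-0.27) fell, with the call of HSPB1 lost without untreated 2, nLDL 2 or nLDL 3 and that of JUN without untreated 1, untreated 2 or nLDL 3 (edgeR adjusted p values of 0.0519 to 0.131).

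**Figure D3:**
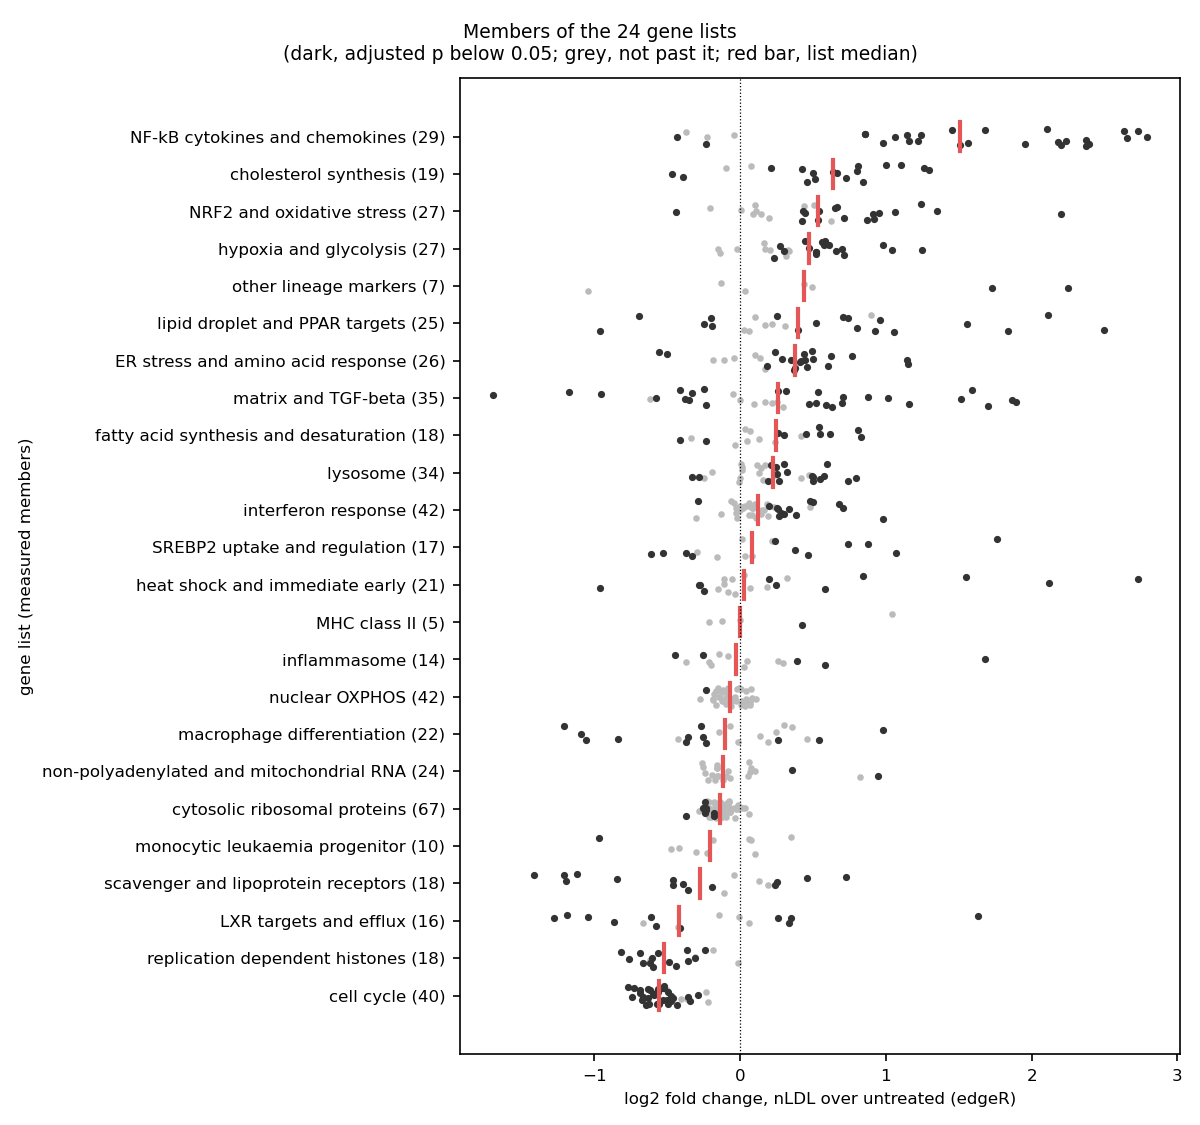
Each point is the log2 fold change (nLDL over untreated, edgeR) of 1 measured member of a gene list, dark where the gene passed and grey where it did not, and each red bar is the list's median. Lists are ordered by median, from the NF-kB list at 1.51 to the cell cycle genes at -0.56. Numbers in parentheses are measured members.

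Proliferation genes were lower in nLDL samples. Of 40 cell cycle genes 35 fell, 0 rose and 5 did not pass, with 36 and 0 adjusted over the list alone (median -0.56, camera adjusted p = 2.09e-15, and adjusted p = 0.14 with an estimated correlation). The replication helicase subunits MCM4 (1.61-fold lower, from 401.1 ± 11.98 to 250 ± 13.2 CPM) and MCM6 (1.53-fold), the nucleotide reductase RRM2 (1.51-fold) and the transcription factor MYBL2 (1.59-fold) were examples. Replication-dependent histone genes fell in 14 of 18 measured members and rose in 0, with 16 and 0 adjusted over the list alone (median -0.52, camera adjusted p = 1.1e-06, and adjusted p = 0.14 with an estimated correlation). They included HIST1H1B (1.69-fold), HIST1H2AG (1.61-fold), HIST1H1C (1.54-fold) and HIST1H4E (1.40-fold), whose single values are uncertain where near-identical histone genes share reads.

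Macrophage differentiation genes rose in 3 of 22 measured members and fell in 9, with 4 and 10 adjusted over the list alone, and the list did not pass (median -0.11, camera adjusted p = 0.22, and adjusted p = 0.32 with an estimated correlation). Over the alternatives this list's median ran from -0.18 to -0.07. The secreted phosphoprotein SPP1 (2.13-fold, from 2522 ± 163 to 1183 ± 89.3 CPM), the integrin ITGAM (2.08-fold) and MSR1 were lower. The Fc receptor FCGR3A (1.97-fold, which shares sequence with a near-identical neighbour), lysozyme LYZ (log2 fold change 0.54) and the protease MMP9 (0.26) rose, with the call of MMP9 lost without untreated 3, nLDL 1 or nLDL 2 (edgeR adjusted p values of 0.0724 to 0.153). CSF1R, the receptor of macrophage growth factor, did not pass (0.14, edgeR adjusted p = 0.108 with Benjamini-Hochberg adjustment), although its groups did not overlap and it passed without the third library of either group (edgeR adjusted p = 0.0337). Of 10 measured genes of monocytic leukaemia progenitors, the transcription factor MYB fell (1.95-fold lower) and no other passed, also when adjusted over the list alone (median -0.21, camera adjusted p = 0.22, and adjusted p = 0.32 with an estimated correlation). Matrix and TGF-beta genes rose in 17 of 35 measured members and fell in 10, with 20 and 10 adjusted over the list alone (median 0.26, camera adjusted p = 0.0155, and adjusted p = 0.20 with an estimated correlation). The protease MMP19 (3.71-fold), the protease inhibitor SERPINE2 (3.25-fold), the proteoglycan VCAN (3.01-fold) and TIMP3 (2.02-fold) rose.

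Cytosolic ribosomal protein genes fell in 9 of 67 measured members and rose in 0, with 4 and 0 adjusted over the list alone (median -0.14, camera adjusted p = 0.000328, and adjusted p = 0.35 with an estimated correlation), and without the third library of either group 27 fell and 1 rose. The median was -0.09 without nLDL 3 and -0.22 with scaling by the total count alone. RPSA (1.29-fold lower), RPLP0 and RPS2 were examples, of which RPLP0 was not called without nLDL 3, and RPS2 not without untreated 1, untreated 2 or nLDL 3 (edgeR adjusted p values of 0.0523 to 0.0979). Of 42 nuclear genes of oxidative phosphorylation only COX5A passed (-0.23), with 0 adjusted over the list alone (median -0.07, camera adjusted p = 0.22, and adjusted p = 0.45 with an estimated correlation), and its call was lost without untreated 2 or any 1 nLDL library (edgeR adjusted p values of 0.0522 to 0.266). Over the alternatives the median of the oxidative phosphorylation list ran from -0.15 to -0.04. Of 5 measured MHC class II genes only CD74 rose (1.34-fold), also when adjusted over the list alone (median 0, camera adjusted p = 0.52, and adjusted p = 0.62 with an estimated correlation). In the list of non-polyadenylated and mitochondrial RNA 2 of 24 measured members rose, the nuclear RNAs NEAT1 (1.92-fold) and MALAT1 (1.28-fold), and 0 fell, with the same counts adjusted over the list alone. Its median was -0.12 while camera put it on the higher side without passing (adjusted p = 0.839, and adjusted p = 0.94 with an estimated correlation). Of 7 measured markers of other lineages COL1A1 (from 4.46 ± 0.676 to 14.5 ± 3.31 CPM) and DCN (from 0.479 ± 0.232 to 2.11 ± 0.601 CPM), both known from fibroblasts, rose and 0 fell, with 3 and 1 adjusted over the list alone (median 0.44, camera adjusted p = 0.22, and adjusted p = 0.32 with an estimated correlation). That median lay between 0.22 and 0.28 without untreated 2, untreated 3, nLDL 2 or nLDL 3, and at 0.03 over 8 measured genes without the third library of either group.

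With an estimated correlation none of the 24 lists passed in camera, against 10 higher and 4 lower with the preset one, and 19 passed in fry, which does not compare a list with other genes. Without the third library of either group, 2201 genes were higher and 1977 lower. All 3521 changed genes that could still be tested had the same direction, and 3320 of them also passed. The libraries kept had contributed to the first calls, so this overlap is not independent evidence.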

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

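Leaving out the third library of both groups, and a term for those libraries, were chosen after the result was seen, and the other settings before. Genes higher and lower numbered 1421 to 2534 and 1279 to 2363 across the other scalings, filters, tests and designs, apart from the thresholds, against 1883 and 1640. At an adjusted p below 0.01 the genes lower numbered 1043, and with a tested fold change of at least 1.5 the counts were 378 higher and 124 lower, because these thresholds are stricter. Leaving out each library in turn gave 1337 to 1944 higher and 1082 to 1791 lower, the lowest without nLDL 2, with fewer samples. The replicate numbers did not pair the samples, since deviations from the group means correlated at 0.18, -0.08 and 0.37 for equal numbers and at -0.36 to 0.28 for unequal ones, and only the third libraries correlated best with their own number. With the replicate number as a block, 2534 genes were higher and 2363 lower, including all 3523 called without it, and a term for the third libraries gave 2509 and 2357.

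The stricter thresholds were applied to the counts only. Of 3109 values of the 164 genes followed under the other settings, 3001 kept their direction and side of the threshold. Of the rest, 91 fell short of it, 13 passed it newly and 4 reversed. The reversed values were near 0, and the cause was not tested. They were ACAT2 at 0.009 without untreated 2 (range -0.156 to 0.009 over the 6 fits that left out a library), and CXCL10, which ranged from -0.173 to 0.072 and was above 0 without untreated 3, nLDL 1 or nLDL 2. APOE passed newly in several settings, among them the replicate block (-0.425, edgeR adjusted p = 4.87e-12). CSF1R passed newly with the replicate block (edgeR adjusted p = 0.0155), with the term for the third libraries (0.00702) and in limma-voom (adjusted p = 0.0406). With an estimated correlation 0 lists were higher and 0 lower against 10 and 4, and the cause was not tested. The matrix list missed the threshold in cameraPR (adjusted p = 0.0547) and the ribosomal list in fry (0.0567), and the LXR list passed with the replicate block (0.0384) and in fry (0.0186). Camera put the list of non-polyadenylated and mitochondrial RNA on the lower side with the replicate block (median -0.09), with the term for the third libraries (-0.1) and in 3 of the 6 fits that left out a library (medians from -0.36 to 0.19 over the 6), the cause of which was not tested. Depth limits the count of calls, since thinning every library to 3675479 reads (20 thinnings) gave 1412 ± 16 higher and 1192 ± 23 lower genes.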

Other observations

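The gene families in the first paragraphs, and the tests of exchanged labels, of the third libraries, of fibroblasts, of a Toll-like receptor agonist and of other splits of the samples, were chosen after the result was seen, while the tests of depth and of GC content and length were set before. Genes that mark maturing dendritic cells rose in 16 of 18 measured members (median log2 fold change 1.72, camera adjusted p = 6.5e-13 over 7 families, and adjusted p = 0.059 with an estimated correlation), a count that is not independent evidence because CCR7, LAMP3 and IDO1 prompted the family. They included the costimulator CD80 (1.92), the chemokine CCL22 (1.99) and the cytokine subunit EBI3 (1.52). FSCN1 (-0.23) and CD86 (0.25) did not pass (edgeR adjusted p values of 0.122 and 0.0647). Without the third library of either group, 17 members of this family rose and 1 fell. BIRC3, TRAF1, RELB and IL12B also belong to the fixed NF-kB list, so part of the rise repeats that list. Genes of interleukin-1 and TNF receptor signalling rose in 11 of 17 and fell in 0 (median 0.48, camera adjusted p = 6.7e-08, and adjusted p = 0.026 with an estimated correlation). Both interleukin-1 receptor genes rose, the signalling receptor IL1R1 (1.71) and the decoy receptor IL1R2 (1.91), as did the kinase IRAK2 (1.67) and BCL3 (1.36). MYD88 (-0.01), IRAK4 (0.02), TRAF6 (0.03), RIPK1 (0.04), TNFRSF1A (0.05) and IL1RAP (0.39) did not pass. The signalling family was also chosen after the result was seen, so its p values are not independent evidence. In the kynurenine pathway of tryptophan breakdown 4 of 9 genes rose (median 0.07, camera adjusted p = 0.024, and adjusted p = 0.20 with an estimated correlation), namely IDO1, IDO2 (2.66), KYNU (1.52) and KMO (0.68), and IDO1 had prompted this family too.

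The 4 other families did not pass. Genes described in lipid-associated macrophages and microglia rose in 7 of 18 and fell in 9 (median -0.24, camera adjusted p = 0.37). Those lower included TREM2, LPL, SPP1 and CX3CR1. Those higher were TMEM119 (1.27), FABP4 (0.96), LGALS3 (0.92), CTSB (0.80), CTSD (0.49), GPNMB (0.25) and TYROBP (0.21). Notch pathway genes rose in 5 of 16 and fell in 2 (median 0.27, camera adjusted p = 0.093). The receptor NOTCH3 (2.23), the ligands DLL1 (2.16) and DLL4 (1.10) and the target genes HES1 (1.11) and HES4 (1.89) rose. HES1 and HES4 were low in untreated samples (3.625 and 1.155 CPM), and the targets NRARP (-0.70), HEYL (0.36) and DTX1 (0.33) did not pass. The ligand JAG1 (-1.01) and the coactivator MAML3 (-0.81) fell. A family of sterol enzyme genes and oxysterol-binding protein genes rose in 4 of 14 members and fell in 3 (median -0.04, camera adjusted p = 0.75). The cholesterol hydroxylase CH25H was lower (-1.72 ± 0.36), and CYP27A1 (0.59) and the vitamin D hydroxylase CYP27B1 (2.35) were higher. Among the binding proteins OSBP (0.25) and OSBPL2 (0.38) rose, and OSBPL1A (-0.35) and OSBPL3 (-0.91) fell. Toll-like receptor genes rose in 0 of 8 and fell in 2 (median -0.27, camera adjusted p = 0.093), the RNA sensor TLR7 (-1.47) and the lipopolysaccharide receptor TLR4 (-0.84). Without the third library of either group, 2 Toll-like receptor genes rose and 2 fell, and 6 Notch pathway genes rose and 4 fell.

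Cholesterol synthesis genes were higher and ABCG1 lower in the samples labelled nLDL, the opposite of what textbook feedback predicts when cells take up LDL cholesterol. With every library thinned to 3675479 reads the list's median stayed at 0.63 (SD 0.023). Thinning keeps the expected shares of reads, so it cannot decide whether lower depth of the nLDL libraries played a part. Leaving out the third libraries gave a median of 0.66, so they were not the cause. Exchanged group labels are a candidate explanation that these data leave open. They would have put lipid droplet genes such as PLIN2 lower under the nLDL label, whereas that list's median was 0.40. The list of LXR targets and efflux genes was split. Its 4 higher members included ABCA1 (0.35) and NR1H3 (1.63), and its 7 lower members included ABCG1, so the lists do not settle the labels. A response of sterol synthesis to inflammatory signalling may also account for the pattern and was not tested.

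The list of cytokines, chemokines and other NF-kB-linked genes had the largest median of the lists. Its median after thinning was 1.51 (SD 0.039), which for the same reason does not decide whether depth played a part. Fibroblasts among the cells were not the source of COL1A1, since they express COL1A1, COL1A2 and COL3A1 all at high levels. The nLDL libraries held 351 reads of COL1A1 and 2 each of COL1A2 and COL3A1, a ratio of 0.011 (upper 95% bound 0.029, for counting error only). However, reads of the fibroblast markers DCN (48 against 13 in untreated libraries) and LUM (7 against 1) were also more numerous. A Toll-like receptor agonist carried by the LDL preparation may have raised these genes and cannot be told apart from an effect of the lipoprotein, because every nLDL sample received the preparation. The interferon list, which many such agonists induce, had a median of 0.13. RNA was taken at a single time, 24 h, so this small median does not decide whether an agonist was present.

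Cell cycle genes were lower with a narrow spread. A trend on GC content and gene length was not the cause, since the median of the 39 members with a GC value was -0.52 (SE 0.03) after the trend was removed and -0.55 before. The third libraries were not the cause, since the median without them was -0.56. A lower share of dividing cells may account for the pattern, as a hypothesis that these bulk libraries do not test. Of the 10 splits of the 6 libraries into 3 and 3, 1 gave as many changed genes, the real one with 3523, and the highest of the others gave 2, and 10 splits are too few for a share under 0.05.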
